A study of Mus musculus with 6 samples.

How the data were processed

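The data are 6 single-colour expression arrays of progenitor B cells sorted by flow cytometry from freshly taken mouse bone marrow, 3 labelled KO and 3 labelled WT. Per the labels' protocols, RNA was extracted from sorted cells, amplified to cDNA with a whole-transcriptome kit for small inputs, labelled with biotin and hybridised, with 1 array per sample. The design text states that the replicates of each genotype are biological. The deposited values are log2 intensities per probe set. Per the submitters' processing notes they were made with RMA, and its version and settings are not given in the sources used here. That the scale is log2 was read from the values, whose array medians lie between 4.94 and 5.06 with nearly equal quartiles. Low signals on such a scale sit close to background, so the fold change of a dim gene is understated. Amplification of small inputs adds noise that the arrays share with the biological spread. Detection calls, array dates and batches were not used here.

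Samples were grouped by the genotype in their labels. Probe sets were named through a table of the platform annotation, which can be old. Of 34760 probe sets, 21640 carried 1 gene symbol, 1321 carried several and 11799 were not listed with a gene. Gene numbers were looked up in a RefSeq gene table of assembly GRCm38.p6, where 21553 were found and 0 symbols changed. Tests used probe sets with 1 symbol and, for 954 genes with several, the probe set with the highest mean over all 6 arrays, which gave 19937 genes. The deposited values were not normalized again for the reported results.

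Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 at default settings, KO minus WT, with Benjamini-Hochberg adjustment over all 19937 genes and a threshold of 0.05. Errors beside the log2 change of a gene or probe set are moderated standard errors, those beside the mean of several genes are standard errors over arrays or over genes, as named, and errors beside a level are SDs over 3 arrays. Erg was also tested with an exact permutation test. Gene lists with at least 5 measured members were tested with camera, with a preset correlation of 0.01 between genes and adjustment over 31 lists, and again with an estimated correlation and with fry. Of 37 lists fixed, those of distal, proximal and intermediate heavy-chain V genes, of light-chain constant and lambda genes and of the mitochondrial genome had 0 measured genes, and the list of sex-linked genes had 4. The planned comparison of distal with proximal heavy-chain V genes therefore was not run, and probe sets that carry heavy-chain or light-chain symbols were tested in its place, in a limma fit over the 22961 listed probe sets.

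The tests, groups, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule names Erg, the 12 largest increases and 12 largest decreases among genes past the threshold whose groups do not overlap, and up to 4 members of each list past the threshold with the largest change. Where none of a list passed, it names the 2 members with the smallest p. It always names Ebf1, Pax5, Rag1, Rag2, Dntt, Igll1, Vpreb1, Il7r, Ighm, Il2ra, Myc, Fli1 and Ets1. Predicted genes with no standard name, microRNA genes and small nucleolar RNA genes are counted and not named by the rule. Of these, 16 passed. Mcm2, Cd3e and the genes of the closing section that are outside the rule were chosen after their values were seen.

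The scripts were tested on simulated arrays for this comparison, with 200 of 19937 genes changed. At a log2 change of 0.5, 10% were recovered; at 1, 62%; at -1, 48%; and at 2, 96%. Of 111 calls 3 were false. Of 2 shifted lists camera called 2, and of 29 others 0. With an estimated correlation it called 1 of the 2. The simulated genes were drawn independently of each other, so these counts do not check camera's calls where the genes of a list move together. Alternatives were other variance models, array weights, renormalization, centring, filters on dim genes, other choices of probe set, stricter thresholds, an ordinary equal-variance test, a block on the replicate number and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.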

Results

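Gene expression was measured on 6 microarrays of progenitor B cells sorted from mouse bone marrow. The sort kept cells that carried B220, CD19 and CD93, had positive to low CD43, and lacked markers of other lineages. In the 3 samples labelled KO, floxed Erg alleles were combined with a Cre transgene named CD2iCre, and the 3 samples labelled WT carried the floxed alleles without it. ERG is a transcription factor of the ETS family. The series title ties it to the joining of V segments to DJ at the immunoglobulin heavy-chain locus (Igh), so the comparison of the genotypes asks which transcripts differ when Erg is targeted in these cells. The median log2 signal of the 6 arrays lay between 4.94 and 5.06. Pairs of arrays within a group correlated at 0.977 to 0.984 across probe sets, and pairs between groups at 0.973 to 0.982. The number of arrays, 3 per group, limits the precision of every value.

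Erg itself was higher in the KO-labelled arrays. Its signal was 9.43 ± 0.23 (SD, n = 3) in the KO-labelled arrays and 8.05 ± 0.65 (SD, n = 3) in the WT-labelled arrays. The single arrays read 9.21, 9.68 and 9.41 for KO and 8.79, 7.75 and 7.61 for WT. The log2 change of Erg was 1.38 ± 0.27 (SE), a 2.61-fold difference (limma, adjusted p = 0.0315). The exact two-sided permutation test gave p = 0.1, the smallest p that 3 arrays against 3 can give. The call of Erg was lost when any 1 of 4 arrays was left out. Adjusted p from limma was 0.113 without KO replicate 2, 0.085 without KO replicate 3, 0.103 without WT replicate 2 and 0.0955 without WT replicate 3. In these 4 fits the log2 change stayed between 1.16 and 1.40, and fewer arrays leave less power. Erg had 1 probe set on the array (10441093). Where its probes lie relative to the deleted part of the gene was not used here, and probes outside the deleted part would not check the genotype. Since the target gene goes against the labels, each direction below is one between arrays labelled KO and arrays labelled WT.

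The largest increase in the KO-labelled arrays was in Il9r, the receptor of interleukin 9. It rose 7.96-fold, from 4.82 ± 0.11 to 7.81 ± 0.40 on the log2 scale (SD, n = 3 per group). Htra3, a secreted serine protease, rose 5.06-fold, from 4.96 ± 0.05 to 7.30 ± 0.15. Sytl2, a protein of vesicle transport, rose 4.53-fold and Adgrl2, an adhesion G protein-coupled receptor, rose 4.15-fold. Cd300c, an activating receptor known from myeloid cells, rose 3.96-fold, and the membrane transporter gene Slc49a4 rose 3.78-fold. Further increases were in Ifitm1 (3.52-fold), the sphingosine-1-phosphate receptor gene S1pr3 (3.39-fold), the early activation marker Cd69 (3.25-fold) and the semaphorin co-receptor gene Nrp1 (3.22-fold). Rbm24 (3.2-fold) and Hoxa5 (3.16-fold) completed the 12 largest among the genes that the rule can name, which leaves out microRNA genes. Their adjusted p values from limma ran from 6.91e-05 for Htra3 to 0.0458 for Rbm24. The largest decreases in the KO-labelled arrays were in the probe sets named Ighg3 (8.59-fold) and Igha (5.29-fold), symbols of heavy-chain constant genes. Both symbols also stand on probe sets that carry V segment symbols. Where the probes lie in the locus was not used here, so a fall of the constant regions themselves is not shown. Nrgn, which encodes a calmodulin-binding protein, was 4.96-fold lower, and Rbpms, which encodes an RNA-binding protein, fell 4.36-fold, from 7.63 ± 0.15 to 5.50 ± 0.07. Mmrn1 (4.06-fold), AF067061 (3.59-fold), the metallothionein gene Mt1 (3.2-fold), the eosinophil granule gene Prg3 (3.03-fold) and the protease inhibitor gene Serpinb1a (2.92-fold) were also lower. The cytokine gene Il18 (2.89-fold), the lymphocyte GTPase gene Gimap4 (2.87-fold) and Tnfrsf19 (2.78-fold) closed the 12 largest decreases under the same rule. Their adjusted p values from limma ran from 9.81e-05 for Rbpms to 0.0460 for AF067061. In all, limma called 564 of 19937 genes (2.83%), of which 275 were higher and 289 lower in the KO-labelled arrays. A change of at least 2-fold was seen in 142 of them, 85 higher and 57 lower. The 2 groups of arrays did not overlap in any of the 564 genes, nor in 20.6% of all genes tested, where chance gives 10%. Of these 24 genes 14 passed whichever array was left out, and Cd69, Rbm24, Igha, Mmrn1, AF067061, Mt1, Prg3, Il18, Gimap4 and Tnfrsf19 missed the threshold without at least 1 array. Without 1 array limma called 559 (KO replicate 1), 105 (KO replicate 2), 272 (KO replicate 3), 230 (WT replicate 1), 236 (WT replicate 2) or 218 (WT replicate 3) genes. An ordinary equal-variance test on the same values called 0 genes, with 2576 at an unadjusted p under 0.05 against 3143 by limma.

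**Figure D1:**
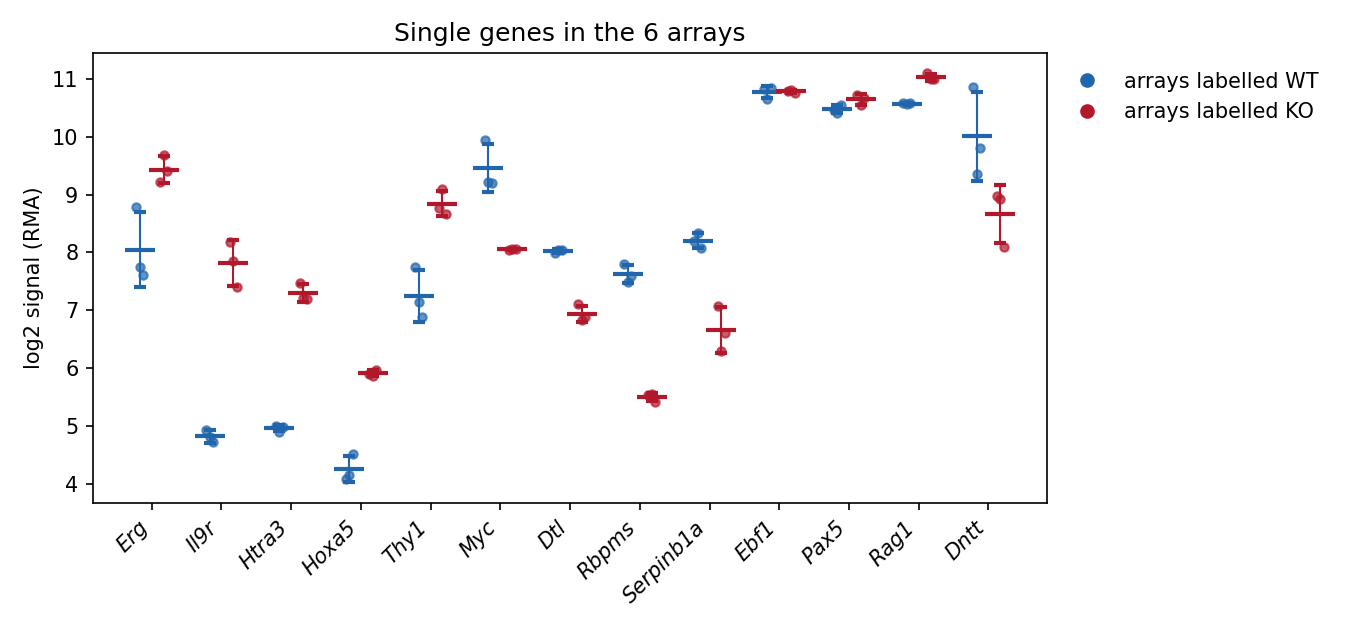
Log2 signal of 13 genes in each array, with WT-labelled arrays in blue and KO-labelled arrays in red. Points are single arrays, bars the group mean and whiskers 1 SD (n = 3). Erg lies higher in the KO-labelled arrays (9.43 against 8.05), while Ebf1 has a log2 change of 0.00.

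Probe sets of the immunoglobulin heavy chain, the locus the series title names, were lower in the KO-labelled arrays. Of 10 heavy-chain probe sets, 9 fell in a limma fit over the 22961 probe sets listed with a gene, and their log2 changes, the tenth included, ran from -4.02 to 0.16 with a mean of -2.37. The 4 that carry V segment symbols beside constant-region symbols all passed, with changes from -3.08 to -2.44. Among them, a probe set shared by Ighg3, Igha, Ighv1-33 and Ighv1-26 read 6.18 ± 0.63 in the KO-labelled and 9.26 ± 0.25 in the WT-labelled arrays (SD, n = 3 per group). The probe sets of Ighm, the constant gene of the mu chain, disagreed. The brightest changed by 0.16 ± 0.17 (SE, adjusted p = 0.752 from limma), while the others changed by -0.98 (adjusted p = 0.0298) and -4.02 (adjusted p = 0.000163). Of 21 light-chain probe sets, 2 rose and 0 fell: 1 shared by Iglv1, Iglc1 and Iglv2 changed by 0.96 and 1 shared by several kappa V symbols by 0.99, and the mean over the 21 was -0.05. This choice of probe sets and of the fit was made after the data were seen. In a fit over all 34760 probe sets, 4 of the 10 heavy-chain probe sets and 0 of the light-chain ones passed, and without WT replicate 3 the first fit called 5 of the 10. Probe sets of these gene families can bind related transcripts, so a value belongs to the family more than to 1 gene.

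**Figure D2:**
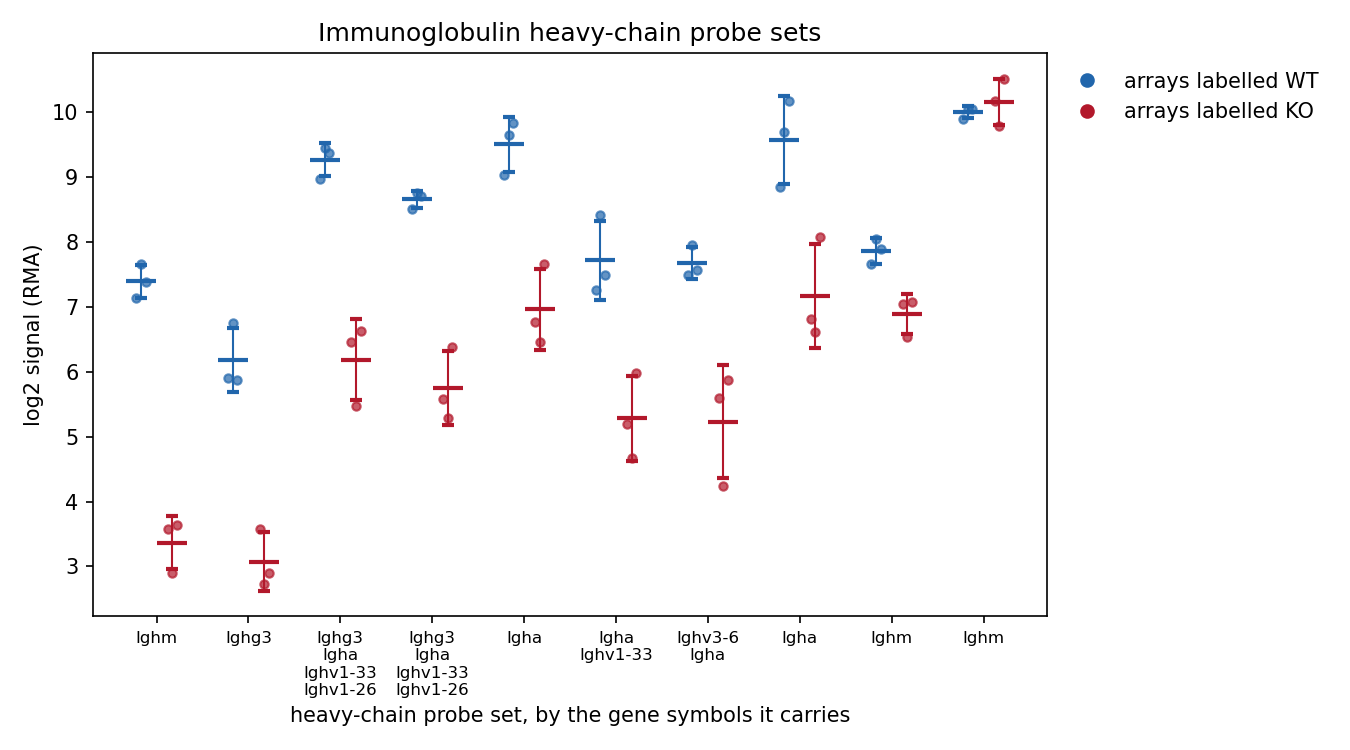
Log2 signal of the 10 heavy-chain probe sets in each array, named by the gene symbols each carries and ordered by log2 change. Points are single arrays, bars the group mean and whiskers 1 SD (n = 3 for WT-labelled arrays in blue and KO-labelled arrays in red). The change runs from -4.02 at the left to 0.16 at the right, both in probe sets of Ighm.

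The transcription factors of B-cell identity did not pass the test. Ebf1, which specifies the B lineage, changed by 0.00 ± 0.11 on the log2 scale (SE, limma, adjusted p = 0.993) and Pax5, which commits cells to it, by 0.17 ± 0.11 (adjusted p = 0.562). Of 24 measured B-lineage transcription factors, 0 passed, over all genes or adjusted over the list alone; the smallest p values were those of Bcl11a (0.52, adjusted p = 0.0837) and Irf8 (0.44, adjusted p = 0.0890). Of 14 genes of V(D)J recombination and end joining, 0 passed over all genes, against 1 higher and 4 lower adjusted over the list alone. The recombinase gene Rag1 changed by 0.45 (adjusted p = 0.0559), its partner Rag2 by 0.15 (adjusted p = 0.630), and Dntt, which adds untemplated bases to the joins, by -1.34 (adjusted p = 0.0789). The surrogate light-chain genes Igll1 (0.36, adjusted p = 0.291) and Vpreb1 (0.26, adjusted p = 0.289) did not pass. Among 21 genes of the pre-B-cell receptor and its signalling, 1 rose over all genes and 1 adjusted over the list alone, in both cases Pik3cd, a kinase subunit (0.65). Limma's camera placed this list higher (adjusted p = 0.00415; adjusted p = 0.266 with an estimated correlation). Among 18 architecture factors of the Igh locus, 1 fell by either adjustment: Wapl, which releases cohesin from DNA, changed by -1.29 ± 0.15 (SE, adjusted p = 0.00384). Camera placed that list lower (adjusted p = 0.000306; adjusted p = 0.293 with an estimated correlation). Of 17 ETS family genes, 1 passed by either adjustment, Erg, and Fli1 (-0.11, adjusted p = 0.811) and Ets1 (0.11, adjusted p = 0.780) did not. Pik3cd missed the threshold without KO replicate 2, KO replicate 3, WT replicate 2 or WT replicate 3, where 0 genes of its list were higher.

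Genes of DNA replication fell together in the KO-labelled arrays. Of 31 measured S phase genes, 23 fell over all genes and 30 adjusted over the list alone, with a mean log2 change of -0.74. The helicase subunit gene Mcm2 is among the 31, and the largest changes were in Dtl (-1.09), Hells (-1.05), Chaf1b (-1.05) and Dscc1 (2.01-fold lower). Camera gave an adjusted p of 8.78e-31 for the list, and the adjusted p = 0.266 with an estimated correlation. Of 41 genes of G2 and M phase, 6 fell over all genes and 34 adjusted over the list alone, with a mean of -0.39. Nek2 (-0.73), Nuf2 (-0.54), Aurka (-0.52) and Ckap2 (-0.52), genes of the mitotic spindle and centrosome, had the largest changes among the 6. Camera called this list lower (adjusted p = 2.10e-21; adjusted p = 0.266 with an estimated correlation). Of 26 replication-dependent histone genes, 1 (H4c3, -0.60) fell over all genes and 9 adjusted over the list alone, with a camera adjusted p of 1.92e-07 (adjusted p = 0.293 with an estimated correlation). The count of S phase genes past the threshold was 2 without KO replicate 2, 13 without KO replicate 3, 7 without WT replicate 1, 9 without WT replicate 2 and 11 without WT replicate 3. For G2 and M phase it was 0 or 1 without any of the 6 arrays. H4c3 missed the threshold without any of the arrays but KO replicate 1. All 31 S phase genes had a change below 0, as had 40 of the 41 genes of G2 and M phase. Neutrophil markers had a mean log2 change of 0.42, but in KO replicate 2 they read 6.65, below WT replicate 1 (6.68) and WT replicate 2 (7.06). Their mean change was 0.64 without KO replicate 2, 0.26 without KO replicate 3 and 0.21 without WT replicate 3.

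Myc fell as well, with part of the genes of growth. Myc, a transcription factor of growth and proliferation, read 8.05 ± 0.0044 in the KO-labelled and 9.46 ± 0.42 in the WT-labelled arrays (SD, n = 3 per group), a change of -1.40 ± 0.19 (SE, limma, adjusted p = 0.00740). Of 18 ribosome biogenesis genes, 5 fell over all genes and 13 adjusted over the list alone. Nop16 (-0.78), Nolc1 (-0.70), Mybbp1a (-0.64) and Nop58 (-0.61) had the largest changes among the 5. Camera called the list lower (adjusted p = 1.28e-11; adjusted p = 0.293 with an estimated correlation). Of 21 genes of glycolysis and of the MTORC1 response, 5 fell over all genes. Adjusted over the list alone, 10 fell and 1 rose. The amino acid transporter gene Slc7a5 (-1.11), the serine and glycine synthesis genes Psat1 (-0.92) and Shmt2 (-0.81) and the glycolytic enzyme gene Tpi1 (-0.70) had the largest changes among those 5 past the threshold over all genes, and the camera adjusted p was 1.98e-09 (adjusted p = 0.283 with an estimated correlation). Of 57 cytosolic ribosomal protein genes, 0 passed by either adjustment, and the list mean was -0.09 (camera, adjusted p = 0.00774; adjusted p = 0.492 with an estimated correlation). Its smallest p values were those of Rpl7l1 (-0.60), which the list took in by its symbol, and Rpsa (-0.31). No gene of ribosome biogenesis passed without KO replicate 2, KO replicate 3, WT replicate 1 or WT replicate 2, where the count was 0, and 1 passed without WT replicate 3. Of the glycolysis and MTORC1 genes 0 fell without KO replicate 2 or WT replicate 1, 2 without KO replicate 3 and 3 without WT replicate 2 or WT replicate 3. Immediate early genes had a mean change of 0.54, and each KO-labelled array lay above each WT-labelled one. Neutrophil markers had a mean change of 0.42, with KO replicate 2 (6.65) below WT replicate 1 (6.68) and WT replicate 2 (7.06). The neutrophil mean was 0.64 without KO replicate 2, 0.26 without KO replicate 3 and 0.21 without WT replicate 3.

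Genes of interleukin 7 receptor signalling went both ways. Of 17 measured genes of this pathway, the one that sustains these progenitors, 3 rose and 1 fell over all genes, against 4 and 3 adjusted over the list alone. Those that rose were the signalling inhibitor genes Socs2 (1.08) and Cish (0.70) and the kinase gene Pim1 (0.92). The receptor gene Il7r changed by 0.19 (adjusted p = 0.623), and camera did not call the list (adjusted p = 0.116). Without KO replicate 1, KO replicate 2, WT replicate 2 or WT replicate 3, 1 gene of the list rose. Part of the genes tied to late pre-B and immature B cells rose. Of 20 measured, 6 rose over all genes, and adjusted over the list alone 10 rose and 2 fell, with a mean of 0.37. The lymphotoxin gene Ltb (1.27), the co-stimulatory receptor gene Cd40 (1.19), the complement regulator gene Cd55 (1.11) and the MHC class II gene H2-Aa (1.09) led the list. Camera gave an adjusted p of 6.83e-05 (adjusted p = 0.337 with an estimated correlation), and Il2ra changed by 0.41 (adjusted p = 0.192). Of 15 genes tied to early pro-B cells, 1 passed over all genes, Bst1 (1.62, 3.08-fold, adjusted p = 0.00740), and adjusted over the list alone 2 were higher and 1 lower (camera, adjusted p = 0.0466; adjusted p = 0.337 with an estimated correlation). The late pre-B list had 3 genes past the threshold without KO replicate 1 and 2 without KO replicate 2 or WT replicate 3. Dendritic cells and macrophages also express Cd40 and MHC class II genes. Markers of plasmacytoid dendritic cells (mean 0.30, 7 of 7 above 0) and of monocytes and macrophages (mean 0.26, 10 of 13) were higher, with each KO-labelled array above each WT-labelled one in list mean. Neutrophil markers (mean 0.42, 13 of 14) were not higher in KO replicate 2, and their mean ran from 0.21 without WT replicate 3 to 0.64 without KO replicate 2, with 0.26 without KO replicate 3. Camera did not call the early list without KO replicate 1, KO replicate 2, WT replicate 2 or WT replicate 3.

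Part of the immediate early genes rose in the KO-labelled arrays. Of 18 immediate early and stress genes, which respond within minutes to stimulation or handling, 5 rose over all genes and 9 adjusted over the list alone. Fos (1.61), Jun (1.07), Klf6 (0.92) and Junb (0.71) had the largest changes among those past the threshold over all genes, and the camera adjusted p was 5.21e-07 (adjusted p = 0.329 with an estimated correlation). Without KO replicate 2 or WT replicate 1 the count was 0, and it was 1 without KO replicate 3, WT replicate 2 or WT replicate 3. The list was highest in KO replicate 2 (7.96), the KO-labelled array where neutrophil markers were lowest (6.65). Of 16 interferon-stimulated genes, 1 rose over all genes, Oas2 (1.53, limma, adjusted p = 0.0121), and 2 adjusted over the list alone. All 16 had a change above 0, against 12 without KO replicate 1. In list mean KO replicate 3 (6.64) lay below WT replicate 1 (6.75), so the groups overlapped. Camera gave this list an adjusted p of 6.19e-05 (adjusted p = 0.329 with an estimated correlation). Of 19 p53 target genes, 1 rose over all genes, the anti-proliferative gene Btg2 (0.70), and 3 adjusted over the list alone (camera, adjusted p = 0.00529; adjusted p = 0.329 with an estimated correlation). Btg2 is also on the immediate early list, and it missed the threshold without KO replicate 2, KO replicate 3, WT replicate 1 or WT replicate 3. Of 14 BCL2 family genes 0 passed over all genes, against 2 higher and 1 lower adjusted over the list alone; Bmf changed by 0.51 (adjusted p = 0.0550) and Bcl2l1 by 0.54 (adjusted p = 0.0560), and camera did not call the list (adjusted p = 0.929). Of 23 adhesion and homing genes, 2 rose over all genes and 3 adjusted over the list alone, led by the receptor genes Gpr183 (1.30) and S1pr1 (0.80), with no camera call (adjusted p = 0.0659). S1pr1 missed the threshold without KO replicate 2, where 1 gene of the list rose. Of 8 kappa V genes with a probe set of their own, 0 passed by either adjustment. Igkv10-96 changed by -0.94 and Igkv8-30 by -0.58, and camera did not call the list (adjusted p = 0.138).

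Markers of other cell types moved with the groups in part, although the sort excluded cells with markers of other lineages. Neutrophil and granulocyte precursor markers were higher in 13 of 14 cases with a mean of 0.42, and 0 passed by either adjustment (camera, adjusted p = 0.00240; adjusted p = 0.416 with an estimated correlation). The neutrophil mean was 0.64 without KO replicate 2, 0.26 without KO replicate 3 and 0.21 without WT replicate 3. S100a9 read 11.2 ± 0.2 in the KO-labelled and 10.7 ± 0.4 in the WT-labelled arrays (SD, n = 3 per group), and Lcn2 changed by 0.62 (adjusted p = 0.335 from limma). Of 13 monocyte and macrophage markers, 1 rose over all genes, the integrin gene Itgam (0.69), and 5 adjusted over the list alone (camera, adjusted p = 0.00415; adjusted p = 0.329 with an estimated correlation). All 7 markers of plasmacytoid dendritic cells had a change above 0. Among them Irf8 (0.44) and Pld4 (0.58) had the smallest p values, 0 passed over all genes and 1 adjusted over the list alone (camera, adjusted p = 0.00725; adjusted p = 0.283 with an estimated correlation). Camera did not call the neutrophil list without KO replicate 3 or WT replicate 3, nor the monocyte list without KO replicate 1 or WT replicate 3. Itgam missed the threshold without KO replicate 2, KO replicate 3, WT replicate 2 or WT replicate 3. Of 12 T cell markers, 1 rose, Thy1 (1.59, 3.01-fold, adjusted p = 0.00740), while Cd3e read 4.82 in both groups; adjusted over the list alone, 1 rose and 2 fell. Of 11 mature B-cell markers, Cd40 and H2-Aa rose and Cd83 (-0.94) fell over all genes, against 2 and 2 adjusted over the list alone. Of 10 stem and multipotent progenitor markers, 2 rose by either adjustment, Hoxa9 (1.13) and Meis1 (0.86). Meis1 missed the threshold without KO replicate 2 or WT replicate 3, and Cd83 without any of the arrays but WT replicate 1. Camera called none of these 3 lists (adjusted p = 0.791, 0.464 and 0.178). Over all genes, 0 markers passed in the NK cell list (11 measured; Nkg7 -0.79 and Klrb1c -0.73), the erythroid list (8; Car1 0.93 and Klf1 -0.23) and the megakaryocyte list (7; Gp5 0.94 and Itga2b 0.31). The same held for plasma cells (8; Derl3 0.41 and Prdm1 0.71) and for stroma and endothelium (11; Lepr 0.26 and Pdgfrb 0.24). Adjusted over the list alone, 1 NK cell marker fell and 0 of the other 4 lists passed. The camera adjusted p values of these 5 lists, in that order, were 0.0855, 0.929, 0.201, 0.276 and 0.185. The mean of the erythroid list (0.07) and its median (-0.01) differ in sign.

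**Figure D3:**
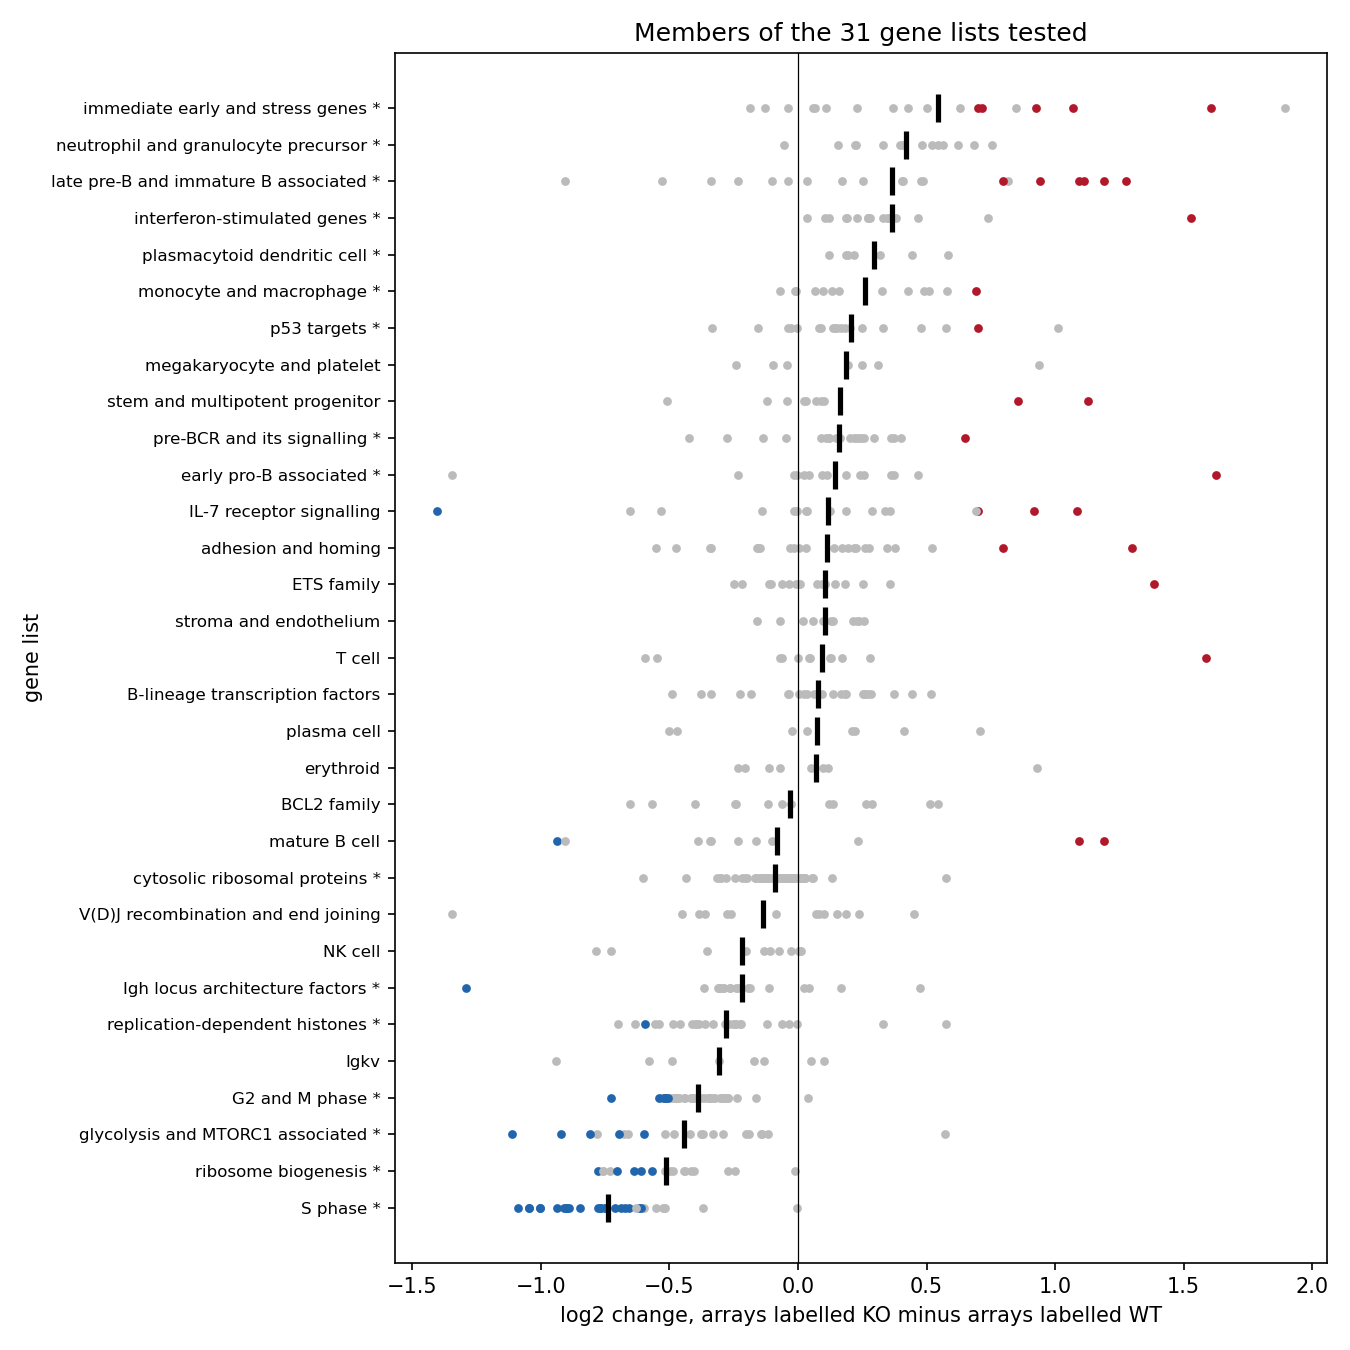
Log2 change of each measured member of the 31 gene lists tested, KO-labelled minus WT-labelled arrays, with 1 row per list. Points are genes, in red or blue where limma's adjusted p was under 0.05 and in grey otherwise; black bars are list means and an asterisk marks the lists that camera called with a preset correlation. S phase lies lowest, with a mean of -0.74, and the immediate early list highest, with 0.54.

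Camera with its preset correlation called 16 of the 31 lists, 9 higher and 7 lower in the KO-labelled arrays. In splits of the 6 arrays that mixed the groups, the same setting still called 4 to 11 lists. With a correlation estimated from the 6 arrays, camera called 0, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.266. Limma's fry, which tests whether the genes of a list move on balance in a common direction, called 8 lists, 7 of them also called by camera. These 7 were S phase, G2 and M phase, histones, glycolysis and MTORC1, architecture factors, pre-B-cell receptor and plasmacytoid dendritic cell markers.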

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

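The tests of explanations in this part were chosen after the results they bear on had been seen. Outside the named genes, 13 probe sets not listed with a gene passed the threshold in a limma fit over all probe sets, 4 higher and 9 lower in the KO-labelled arrays. They stand out because no comparison above uses them, and no explanation was tested.

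Erg was higher in the KO-labelled arrays by 1.38 (log2), the direction opposite to a loss of its transcript. A single array swapped between the groups was tested by the first principal component of all genes, which holds 42.1% of the variance: 0 arrays lay nearer the other group's mean, which argues against it. An exchange of all labels would raise the V-carrying heavy-chain probe sets in the KO-labelled arrays, given the role in V-to-DJ joining that the title states. They were lower by a mean of -2.71 ± 0.41 (SE over arrays, 4 probe sets). These 4 also carry constant-region symbols, and the Ighg3 probe set without V symbols changed by -3.10. They are thus not shown to read V segment transcripts, and their fall was known when this check was chosen. The check therefore cannot decide on an exchange of all labels, which stays open. It also stays open whether the Erg probe set reads sequence outside the deleted part. A biological rise of a transcript that lacks the deleted part is an untested hypothesis.

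Genes known from other cells, Tyrobp (1.32), Cd300c (1.98) and Thy1 (1.59), were higher in the KO-labelled arrays. Neutrophil and monocyte markers above the median level were higher in 16 of 18 cases, by 0.41 ± 0.25 (SE over arrays), with S100a8 the most abundant at 11.4. As the whole cause, RNA of neutrophils or monocytes would raise these markers by about the 1.65 of Tyrobp and Cd300c, and 2 SE reach 0.91, which argues against it, although both genes were picked for their size; a share stays open. The other 22 T and NK cell markers changed by -0.13 ± 0.08 (SE over arrays), with Lat the most abundant at 6.90 and Cd3e at 4.82, which argues against T or NK cells for Thy1. RNA of dendritic cells was not tested in this way, and all 7 markers of plasmacytoid dendritic cells had a change above 0 (mean 0.30), so it stays open. The sort removed lineage-marked cells, and a change of Tyrobp, Cd300c and Thy1 within progenitor B cells of the KO-labelled mice is an open hypothesis.

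Cell-cycle genes were lower in the KO-labelled arrays, with a mean of -0.74 for S phase. Against 10000 random lists matched on signal level the S phase mean was lower by 0.69 (difference -0.69, SD of the lists 0.06), which argues against a bias that depends on signal level. A sort with fewer pre-B cells could raise early pro-B genes relative to genes of late pre-B and immature B cells. The difference, early minus late, was -0.22 ± 0.25 (SE over arrays), and the error spans 0. The late list also covers immature B cells, so this contrast does not isolate pre-B cells. A shift in the mix of stages, in either direction, therefore cannot be told apart from slower cycling. The genotype itself stays among the open explanations.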

How the results depend on the processing

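Erg stayed higher in the KO-labelled arrays, with limma's adjusted p between 0.0240 and 0.0441 over 10 model, scaling, filter, probe and block settings, and missed the threshold in the ordinary equal-variance test (1.38, adjusted p = 0.317). Leaving out each array, its log2 change ran from 1.16 to 1.75. The count of 564 genes (275 higher, 289 lower) ran from 105 to 559 (78 to 226 higher, 27 to 333 lower) with 1 array left out, where fewer arrays leave less power. It became 142 (85 and 57) at 2-fold or more, 81 (56 and 25) at an adjusted p under 0.01 and 0 (0 and 0) in the ordinary test, whose smallest adjusted p was 0.0618. Median centring left 409 genes, with 175 higher, of which 406 were among the 564; the cause was not tested. Over all probe sets 39 passed (21 and 18). Probe sets not listed with a gene had a median residual SD of 0.280 against 0.164 in listed ones, and the prior degrees of freedom fell from 5.87 to 2.67. The other model, scaling, filter and probe settings gave 553 to 746 genes. Heavy-chain probe sets called lower went from 9 to 4 in the fit over all probe sets, and ran from 5 to 8 with 1 array left out. Ighm turned to -1.61 with the mean of its probe sets and to -4.02 with the most variable one, since its probe sets disagree. Lists called went from 16 to 0 with an estimated correlation, the only camera setting that changed. They went to 8 with fry, for which the cause was not tested, and the other settings gave 14 to 20. Of the 66 named genes past the threshold, 39 missed it without KO replicate 2, and 14 to 28 without another array. The residuals of arrays with the same replicate number correlated at 0.212 (replicate 1), -0.0728 (replicate 2) and 0.128 (replicate 3). The same number gave the highest correlation for KO replicate 1 and KO replicate 3, while KO replicate 2 correlated best with WT replicate 3. With 3 arrays per group, these values cannot decide whether the numbers pair the arrays or mark a shared batch. With the replicate number as a block limma called 710 genes, 503 of them shared, and 16 lists. The distal and proximal V gene comparison and its alternatives were not run, for lack of probe sets with 1 symbol. Erg has 1 probe set, so probe-wise values add nothing. The heavy-chain sets, the list tests with the most variable probe set or with centring, and list counts with 1 array left out were chosen after seeing the data. Genes with signals near the array floor are limited by signal over background.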

Other observations

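The tests on NF-kB targets and other Hoxa genes were set before their values were seen, apart from Icam1, tested above among the adhesion genes. The other values here were picked after. Several genes of the NF-kB pathway, picked for their rise, were higher in the KO-labelled arrays. Nfkb2, a subunit of the alternative pathway, rose by 0.90 ± 0.12 (log2, SE, limma, adjusted p = 0.00740), the inhibitor of apoptosis gene Birc3 by 0.83 and the kinase gene Map3k8 by 1.13, beside Cd40 (1.19) and Cd69 (1.70). The 17 other measured target genes were listed before their values were seen, apart from Icam1. Of these 17, the inhibitor genes Nfkbia (0.63) and Tnfaip3 (0.71) and the gene Bcl3 (0.57) also passed. The mean of the 17 was 0.26, above 0 by more than 2 SE by either error (SE over genes 0.09, SE over the arrays' mean values 0.05). Genes of a pathway are not independent replicates. The value is consistent with a wider rise of NF-kB targets as a hypothesis. Tnf (-0.13), Ccl3 (-0.22), Ccl4 (-0.25), Tnfaip2 (-0.12) and Tnip1 (-0.14) did not pass and had changes below 0. The immediate early genes, which handling can raise, were also higher in the KO-labelled arrays. The means of both sets were highest in KO replicate 2. Among the WT-labelled arrays, WT replicate 1 was highest for the NF-kB targets and lowest for the immediate early genes.

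Part of the homeobox genes of the Hoxa cluster, known from early progenitors, were higher too. Hoxa5 changed by 1.66 and Hoxa9 by 1.13. The mean of the 8 other Hoxa genes, a test set before their values were seen, was 0.38, above 0 by more than 2 SE by either error (SE over genes 0.16, SE over the arrays' mean values 0.09). Neighbouring genes are not independent replicates. Hoxa3 (0.83) and Hoxa6 (1.08) passed. Hoxa7 (0.69), Hoxa2 (0.34), Hoxa11 (0.22), Hoxa4 (0.09), Hoxa10 (0.08) and Hoxa13 (-0.32) did not. The group means of Hoxa2, Hoxa10, Hoxa11 and Hoxa13 lay between 3.53 and 4.69, below the array medians. At such levels the values of these genes cannot show whether they share the rise. Hoxa3 was also dim (4.05 in the WT-labelled arrays), while Hoxa4 (5.91 there) lay above the medians. The change of Hoxa4 was 0.09 ± 0.14 (SE), so the rise was not seen in every member with a readable signal. This rests on 1 gene. Meis1, a cofactor of Hox proteins, changed by 0.86.

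Some precursors of the microRNA cluster that holds Mir17, a known target of Myc, rose while Myc fell. Mir20a rose by 1.68 (adjusted p = 0.0123 from limma) and Mir19a by 1.57 (adjusted p = 0.00875 from limma), while Myc changed by -1.40. Mir19b-1 (1.34, adjusted p = 0.0620 from limma), Mir17 (0.48) and Mir18 (0.37) did not pass. In the WT-labelled arrays Mir19a read 2.23, below the arrays' lower quartiles, and Mir20a 4.71, below their medians. Both rises therefore start from dim signals. The host transcript Mir17hg changed by -0.54 (adjusted p = 0.526). Other genes with clear differences were the transcription factor gene Klf3, which rose by 1.39 ± 0.13 (SE), and the replication gene Gins1, with a change of -1.04 ± 0.14.

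Xist, expressed from the inactive X chromosome, read 9.82 to 10.4 over the 6 arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty read at most 2.30, 3.57 and 2.86, with no change between the groups past the threshold.

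Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 564 genes, and the highest of the others 0, so 1 of the 10 splits, the real one, gave as many genes. For lists the real split gave 16 and the others 4 to 11, so 1 split gave as many. Camera with its preset correlation thus called lists in every mixed split, although no gene passed there. A list call at that setting is therefore weaker evidence of a group difference than its adjusted p implies.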
